A study of Homo sapiens with 4 samples.

How the data were processed

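Total RNA of MDA-MB-231 cells grown in medium with 10% fetal bovine serum and transfected with a FOXC1 plasmid or the vector was amplified from 100 ng and hybridised to Affymetrix human whole-transcript gene arrays, 2 per group and 4 in all. Per the labels, the authors summarised the probes with the PLIER algorithm in Affymetrix Expression Console at gene level. The deposited values are intensity on a linear scale, as PLIER signal, and their normalization options, background step and software versions are not given in the sources used here. The values were used as deposited. PLIER signal can approach 0 for dim probe sets, so that log ratios of dim transcripts are unstable. The lowest signals were near 0 (4.78e-05 in vector replicate 1), and between 2.67% and 2.92% of probe sets per array lay below 16. For that reason 16 was added before taking log2, which shrinks the folds of dim transcripts. No detection calls were used, and the arrays carry no read depth, so that precision is set by the 2 arrays per group. Probes of 1 probe set can also bind related transcripts, and changes were computed within probe sets. Signal levels of different probe sets were ranked to pick 1 per gene and to set limits of brightness.

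Groups and replicate numbers were taken from the labels, which describe the arrays as biological replicates. Whether the transfection was transient or stable, in pools or clones, is not given in the sources used here. The p-values measure spread between the arrays of a group, which may not cover the spread between separate transfections. The replicate deviations of arrays with the same number did not go together between groups (correlation across probe sets -0.02), and the numbers were used as a block only as an alternative. Of 33297 probe sets 21214 carried at least 1 gene symbol, 19460 of them 1 symbol and 1754 several, and 12083 carried none. The unnamed ones were left out of the comparison and used only in a fit over all rows. The transfected gene itself was not analysed here.

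The 21214 probe sets were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean log2 signal, two-sided), with 2 residual degrees of freedom and 18.1 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg at 0.05. Gene level counts use probe sets with 1 symbol and 1 probe set per symbol, the one with the highest mean over the 4 arrays, for 18417 genes. Signals are given as mean ± SD of the linear values, while folds are 2 to the power of the log2 difference from the fit.

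Before the data were examined, 35 lists with 758 different genes were fixed, of which 691 were measured. They cover genes tied to FOXC1, forkhead factors, the Hedgehog, Notch, Wnt, TGF-beta and BMP, EGFR and MAPK, NF-kB, interferon and p53 pathways, epithelial, luminal, basal and mesenchymal genes, matrix, integrins, chemokines and their receptors, antigen presentation, angiogenesis, the cell cycle, stress, metabolism, stem cell genes, expression controls and markers of 4 other cell types. Each was tested with camera in limma against all other genes with a preset correlation of 0.01, adjusted over the 35 lists. Camera was also run with an estimated correlation, and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. Members were also counted with p adjusted over the list alone. None of the lists is known to have been chosen on these samples.

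The rule for named genes was fixed before the data were examined. It takes the 14 largest rises and the 14 largest falls among genes that passed, whose FOXC1 arrays both lay on one side of both vector arrays, and whose higher group mean lay above the 25th percentile of all tested probe sets (a signal of 275). Olfactory receptor, small RNA, microRNA, keratin associated and uncharacterised LOC genes were left out of the rule and counted as families. It adds up to 4 members of each list, those that passed with the largest change first.

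The fit was tested on simulated data of the same size. Of 50 simulated changes at each size, 54% were recovered at a log2 change of 0.25, 96% at 0.5 and 100% at 1 and at 2, with 7 false calls (3.85% of calls). In data with no change 0 probe sets were called. The simulated noise was independent between probe sets and arrays, and few probe sets were changed, so that these rates may not hold for the real arrays.

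The alternatives tried were offsets of 1 and 64, filters at the 25th and 50th percentile of signal, quantile normalization and median centring, eBayes without a trend and with robust moderation, the replicate number as a block, leaving out each array in turn, averaging the probe sets of a gene, all rows, an adjusted p of 0.10, and a log2 limit of 1. A gene table of the human reference assembly served to order genes along the chromosomes for a comparison of neighbouring genes.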

Results

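The series measured gene expression in MDA-MB-231 cells, a human breast cancer cell line of basal-like character, after transfection with a plasmid for the forkhead transcription factor FOXC1 or with the control vector. RNA from 2 FOXC1-transfected and 2 vector samples, which the labels call biological replicates, was hybridised to 4 Affymetrix whole-transcript arrays. Each array gave a linear PLIER signal for 33297 probe sets. The median signal was 493 and 489 in the vector arrays and 499 and 512 in the FOXC1 arrays. Across probe sets, which are not independent replicates, the Pearson correlation of log2 signal was 0.997 within each group and 0.992 between arrays of different groups. Precision is limited by the number of arrays. All folds and log2 values below compare FOXC1 with vector on the scale of log2(signal + 16).

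The question of the comparison was which transcripts differ between FOXC1-transfected and vector cells. The fatty acid carrier FABP4 rose 31.8-fold, from a signal of 35.0 ± 3.20 in vector to 1609 ± 124 in FOXC1 cells (SD, n = 2), and the cytokine receptor IL1RL1 rose 23.4-fold, from 88.0 ± 2.05 to 2414 ± 155 (SD, n = 2). HHIP, which binds and restrains Hedgehog ligands, rose 20.2-fold, from 251 ± 0.59 to 5380 ± 165 (SD, n = 2). In the other direction, the kinase CDK15 fell 21.0-fold, from 4686 ± 175 to 208 ± 11.9 (SD, n = 2), the tight junction protein CLDN4 fell 13.0-fold, from 687 ± 22.4 to 37.9 ± 2.57 (SD, n = 2), and the adhesion protein CDH11 fell 12.2-fold, from 3523 ± 205 to 274 ± 11.9 (SD, n = 2). The limma adjusted p of these 6 genes was 5.73e-17 or lower. The FOXC1 transcript itself was not analysed here, so the labels were not checked against the transfected gene.

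The other genes with the largest rises were AADAC (14.7-fold), ANKRD30B (12.7-fold), AMTN (10.1-fold), CLTRN (9.17-fold), MYCT1 (7.89-fold), the thrombin receptor family member F2RL2 (6.70-fold), the ephrin receptor EPHA3 (5.42-fold), FAM230B (5.29-fold), TNFSF18 (4.86-fold), the fibrinogen chain FGB (4.74-fold) and SPX (4.67-fold). The other large falls were in TMLHE (14.9-fold), MPZL2 (9.77-fold), ADGRE1 (9.47-fold), the long noncoding RNA UCA1 (8.48-fold), CD96 (7.36-fold), TENM1 (7.10-fold), the class II antigen presentation genes HLA-DPA1 (6.09-fold) and HLA-DPB1 (5.60-fold), the adhesion molecule MCAM (5.89-fold), VAV1 (5.40-fold) and the laminin-binding integrin chain ITGB4 (5.32-fold). The vector signals of FAM230B were 338 and 938, its fold was 3.22 without vector replicate 1 and 8.69 without vector replicate 2, and its call was lost with robust variance moderation (adjusted p = 0.148). AADAC in vector cells (8.89 ± 0.53) and TMLHE in FOXC1 cells (10.2 ± 4.70; SD, n = 2 each) lay below the offset of 16, so that their folds depend on it. They were 35.4 and 34.8 with an offset of 1 and 5.67 and 5.88 with an offset of 64. With an offset of 64 the folds of FABP4 (16.9), ANKRD30B (8.08), AMTN (6.63), CLDN4 (7.37), MPZL2 (5.42), ADGRE1 (5.68) and VAV1 (3.34) were also lower by more than 1.5 times.

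**Figure D1:**
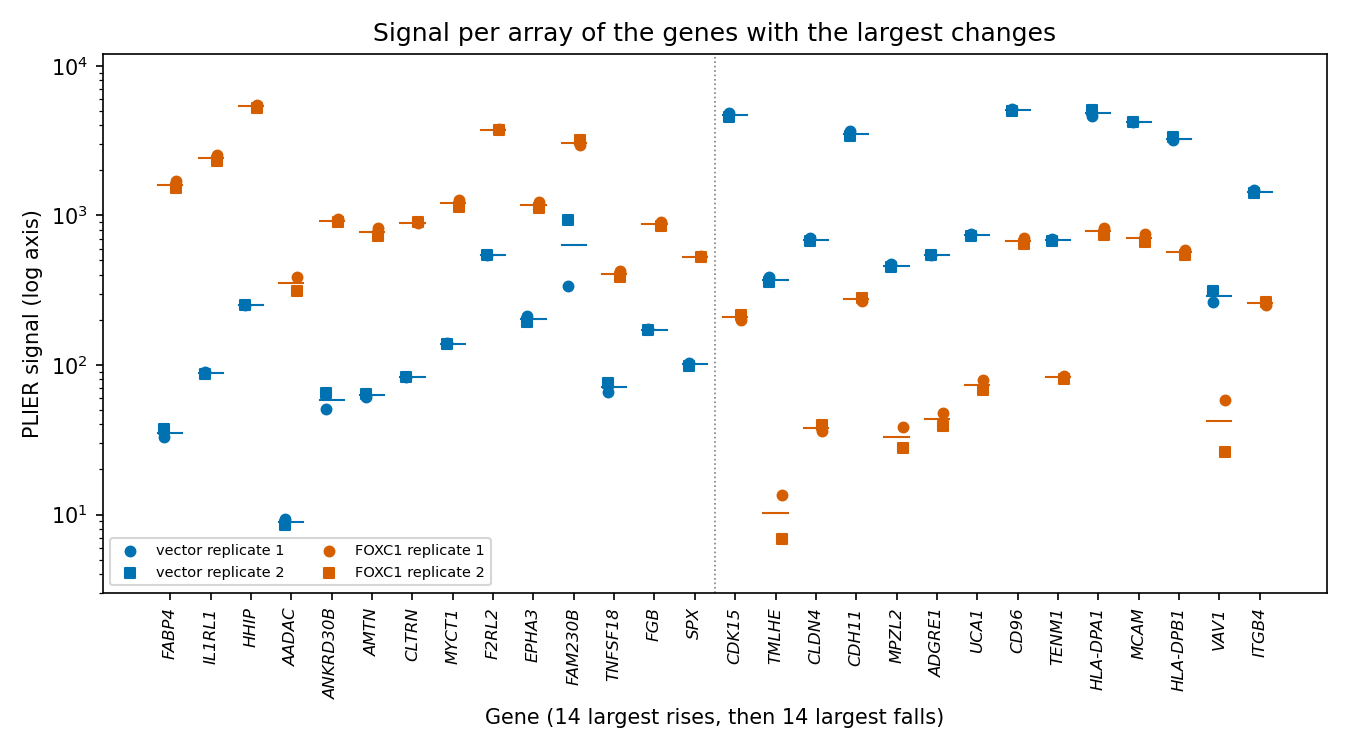
PLIER signal (log axis) in each of the 4 arrays for the 14 genes with the largest rises and the 14 with the largest falls; points are single arrays and short lines are group means. Genes were picked among those whose FOXC1 arrays both lie on one side of both vector arrays. The 2 vector arrays of FAM230B stand apart at 338 and 938.

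Of 18417 genes with 1 probe set each, 5777 passed an adjusted p of 0.05 in limma, 2925 higher and 2852 lower in FOXC1 cells. Most of these changes were small, with a median absolute log2 change of 0.24 among the called genes. Changes of at least 2-fold numbered 50 higher and 127 lower. Changes of at least 8-fold numbered 7 in each direction, but 8 higher and 9 lower with an offset of 1 and 4 higher and 2 lower with an offset of 64. Centring each array on its median moved the balance of directions to 1739 higher and 3396 lower. Variance moderation without a trend on signal called 1461 higher and 1790 lower, 1913 genes were called higher without vector replicate 2, and a fit over all probe sets, unnamed ones included, called 1858 higher.

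Gene lists were fixed before the data were examined, and each was tested with camera, from limma, with a preset inter-gene correlation. Of the 35 lists, 17 passed, 4 of them higher and 13 lower. With the correlation estimated from the 4 arrays 0 lists passed, and that p is given beside each call. That test has 2 residual degrees of freedom. Lists with an estimated correlation below the preset one lost their call too, such as luminal breast genes (-0.046). The loss is therefore not explained by inter-gene correlation alone and cannot decide whether the lists moved. The calls rest on the preset correlation. In other called lists the estimated correlation was above the preset one. It was 0.369 for cholesterol synthesis, 0.31 for p53 targets, 0.158 for NF-kB targets and 0.101 for hypoxia and glycolysis. The camera p-values of such lists with the preset correlation may therefore be too small. Members outside the rule for named genes that complete a count of 5 or fewer were picked after their values were seen.

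More epithelial genes fell than rose in FOXC1 cells. Of 21 measured epithelial junction genes, 10 fell and 2 rose (11 and 3 adjusted over the list alone). Besides CLDN4, the falls included CLDN7 (3.02-fold) and the adhesion molecule EPCAM (1.49-fold, log2 -0.58 ± 0.06 SE), and the 2 rises were CLDN1 (2.07-fold) and CLDN3. The list passed camera with an adjusted p of 0.000976 (adjusted p = 0.29 with an estimated correlation). E-cadherin, CDH1, did not pass (log2 0.03 ± 0.09 SE). Its signals of 274 in vector and 280 in FOXC1 cells lay near the limit of brightness of 275, so that a fall may not have been visible. Luminal breast genes fell in 8 of 19 and rose in 0 (9 and 0 adjusted over the list alone), with a camera adjusted p of 0.000574 (adjusted p = 0.29 with an estimated correlation). Among them were the luminal transcription factors SPDEF (5.11-fold lower) and FOXA1 (2.55-fold lower), carbonic anhydrase CA12 (1.43-fold lower) and MLPH (1.33-fold lower). Markers chosen for luminal epithelial cells as another cell type moved the same way, with 7 of 14 lower and CLDN3 alone higher (7 and 2 adjusted over the list alone). Their camera adjusted p was 0.000283 (adjusted p = 0.29 with an estimated correlation), and 11 of the 14 also stand in other lists.

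Basal-like breast genes were mixed, with ID4 and EGFR higher and LAMB3, SOX9, CAV1, ITGA6 and ITGB4 lower among 15 measured, the same counts adjusted over the list alone. The list did not pass camera (adjusted p = 0.143), and its median log2 change of 0.03 had the opposite sign to its mean of -0.14. It passed, lower, without FOXC1 replicate 2 (adjusted p = 0.0391), without vector replicate 1 (0.011), without vector replicate 2 (0.0173), with the replicate number as a block (0.0209), with median centring (0.0152) and with fry (0.0389). Of 24 genes of the epithelial to mesenchymal transition 4 rose and 6 fell, the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.396). The actin-binding protein TAGLN rose 1.86-fold, PRRX1 1.24-fold, MMP3 1.22-fold and LOX 1.14-fold, while the matrix protein TGFBI fell 2.14-fold and S100A4 fell 2.40-fold. The call of PRRX1 was lost without FOXC1 replicate 1 (log2 0.28) and without vector replicate 1 (log2 0.18), with quantile normalization (adjusted p = 0.0786) and without a variance trend (0.0932).

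Genes of matrix attachment and matrix breakdown moved in both directions. Among 25 integrin and matrix genes, 10 fell and 6 rose (12 and 6 adjusted over the list alone). The falls included ITGB4, ITGB8 (3.16-fold), the laminin chain LAMA5 (1.88-fold) and tenascin C, TNC (1.78-fold). The camera adjusted p was 0.00713 (adjusted p = 0.29 with an estimated correlation), and the call was lost among probe sets above the 50th percentile of signal (adjusted p = 0.128). Of 24 matrix metalloproteinases and inhibitors, 7 fell and 5 rose (7 and 5 adjusted over the list alone), with a camera adjusted p of 0.0307 (adjusted p = 0.29 with an estimated correlation). The collagenase MMP1 rose 2.76-fold, from 4781 ± 137 to 13240 ± 92.5 (SD, n = 2), and MMP7 (1.98-fold), MMP10, MMP3 and the urokinase receptor PLAUR also rose. The signals of MMP7, MMP10 and MMP3 lay below the limit of brightness of 275 in both groups. The metalloproteinase inhibitors TIMP3 (2.58-fold) and TIMP4 (2.45-fold) fell. The call of this list was lost without a variance trend (adjusted p = 0.145).

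More NF-kB targets rose than fell. Of 24 measured, 15 rose and 2 fell (17 and 2 adjusted over the list alone), with a median log2 change of 0.25 and a camera adjusted p of 1.42e-07 (adjusted p = 0.29 with an estimated correlation). The adhesion molecule ICAM1 rose 3.70-fold (log2 1.89 ± 0.05 SE), and the chemokines CCL20, CXCL1 and CXCL8 rose 3.50-fold, 2.23-fold and 2.18-fold. CCL20 was dim in vector cells (34.6 ± 1.66; SD, n = 2), and its fold was 4.56 with an offset of 1 and 2.28 with an offset of 64. The 2 falls were in BCL3 and TNFAIP2. Of 26 chemokines and cytokines 10 rose and 5 fell, namely IL1A (2.09-fold), CSF3, CSF1, IL11 and IL24, the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.138). It passed, higher, without vector replicate 1 (adjusted p = 0.000219), without vector replicate 2 (4.37e-05), with the replicate number as a block (0.00296), with median centring (0.00457) and with fry (0.0306). Of 16 chemokine receptors CCR10 rose 1.14-fold and CXCR4 and CCR1 (1.28-fold) fell, the same counts adjusted over the list alone, and the camera adjusted p was 0.932. This list had a mean near 0, a positive median of 0.02 and a camera direction of lower. The calls of CCR10 and CCR1 were each lost without vector replicate 1 (log2 0.15 and -0.38) and without vector replicate 2 (log2 0.23 and -0.34), and that of CCR10 also without FOXC1 replicate 2 (log2 0.17), with median centring (adjusted p = 0.12) and without a variance trend (0.0664).

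More interferon response and antigen presentation genes fell than rose. Of 34 interferon response genes, 15 fell and 2, OAS1 and OAS3, rose (15 and 3 adjusted over the list alone). The antiviral protein MX2 fell 2.11-fold, IFI44L 2.10-fold, the tetherin gene BST2 2.04-fold and PARP14 2.00-fold. The camera adjusted p was 0.000211 (adjusted p = 0.42 with an estimated correlation). Of 13 measured antigen presentation genes 9 fell and TAP2 rose (10 and 2 adjusted over the list alone), with a camera adjusted p of 1.36e-05 (adjusted p = 0.29 with an estimated correlation). The peptide loading genes HLA-DMB and HLA-DMA fell 2.69-fold and 2.48-fold, the immunoproteasome subunit PSMB9 fell 1.75-fold, and the peptide transporter subunit TAP1 fell as well. Under 5 of the 13 genes lay outside blocks of neighbouring genes that shift together, so the list was not tested without those blocks. A regional shift and a fall of the list cannot be told apart here.

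More hypoxia-related and growth factor response genes fell than rose as well. Of 26 hypoxia and glycolysis genes 18 fell and the peptide hormone gene ADM rose (20 and 1 adjusted over the list alone), with a median log2 change of -0.25 and a camera adjusted p of 3.25e-11 (adjusted p = 0.29 with an estimated correlation). The angiogenic factor VEGFA fell 3.20-fold, from 6680 ± 186 to 2077 ± 11.2 (SD, n = 2), NDRG1 3.07-fold, PFKFB4 1.76-fold and ANGPTL4 1.61-fold. Of 24 angiogenesis genes 10 fell and 6 rose, the same counts adjusted over the list alone. Besides VEGFA and ANGPTL4, the ephrin EFNB2 (1.80-fold) and the receptor KDR (1.75-fold) fell, and the camera adjusted p was 0.0264 (adjusted p = 0.29 with an estimated correlation). Of 27 immediate early genes 19 fell (20 adjusted over the list alone), and IER3 and CCN1 rose. FOSB and FOS, subunits of the AP-1 transcription factor, fell 2.17-fold and 2.14-fold, NR4A2 1.60-fold and ZFP36 1.47-fold, with a camera adjusted p of 5.74e-10 (adjusted p = 0.29 with an estimated correlation). Of 22 genes of the EGFR and MAPK pathway 14 fell and EGFR rose (15 and 1 adjusted over the list alone). The ETS factor ETV1 fell 1.92-fold, the EGFR ligands TGFA 1.85-fold and EREG 1.60-fold, and the feedback inhibitor SPRY1 1.70-fold, with a camera adjusted p of 7.2e-08 (adjusted p = 0.29 with an estimated correlation). The angiogenesis call was lost among probe sets above the 50th percentile of signal (adjusted p = 0.0921) and without a variance trend (0.052).

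**Figure D2:**
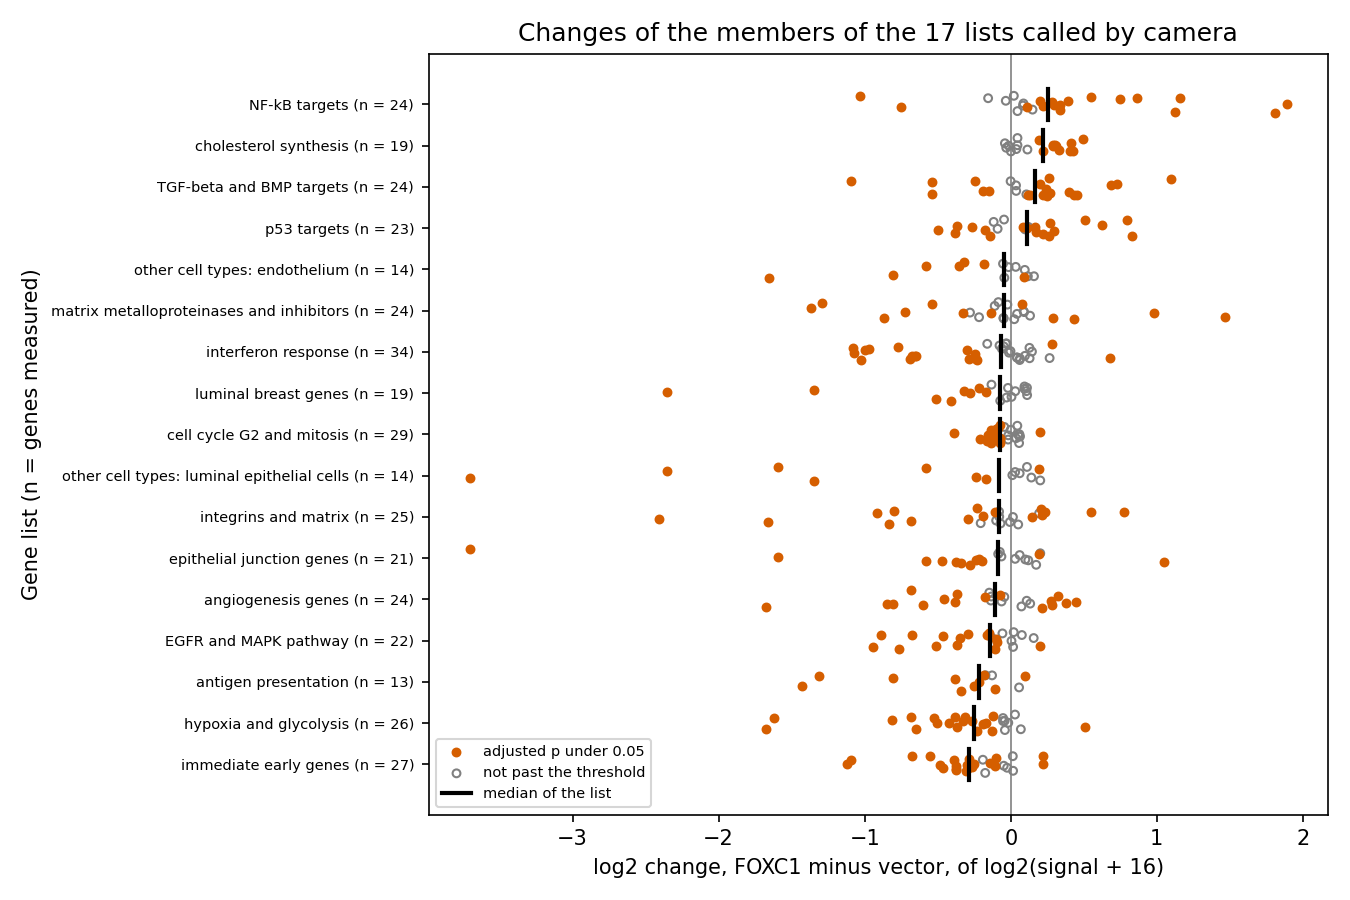
Log2 change (FOXC1 minus vector) of each measured member of the 17 gene lists that passed camera; each point is 1 gene, filled where it passed an adjusted p of 0.05 and open where it did not, and the vertical bars are list medians. Medians range from -0.29 for immediate early genes to 0.25 for NF-kB targets.

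Cholesterol synthesis genes rose in 11 of 19 and fell in 0 (12 and 0 adjusted over the list alone). The regulator INSIG1 rose 1.41-fold and the enzymes HMGCS1, CYP51A1 and MSMO1 rose 1.34-fold, 1.33-fold and 1.32-fold. The camera adjusted p was 2.42e-05 (adjusted p = 0.44 with an estimated correlation). Of 24 TGF-beta and BMP targets 14 rose and 6 fell, the same counts adjusted over the list alone, with a camera adjusted p of 0.0262 (adjusted p = 0.29 with an estimated correlation). The activin chain INHBA rose 2.13-fold, ID3 1.66-fold and SKIL 1.61-fold, while TGFBI fell. This call was lost among probe sets above the 50th percentile of signal (adjusted p = 0.0526) and without a variance trend (0.0766). Of 23 p53 targets 12 rose and 6 fell (14 and 6 adjusted over the list alone), with a camera adjusted p of 0.0419 (adjusted p = 0.66 with an estimated correlation). The DNA damage recognition gene DDB2 rose 1.78-fold, GDF15 1.74-fold, GADD45A 1.54-fold and the BH3-only gene PMAIP1 1.42-fold. MDA-MB-231 cells are known to carry mutant p53. This call was lost without FOXC1 replicate 1 (adjusted p = 0.123), without a variance trend (0.361), with fry (0.0662) and without the genes of neighbouring blocks that shift together (0.202), an alternative chosen after seeing the data.

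More cell cycle genes of G2 and mitosis fell than rose, by small amounts. Of 29 measured 16 fell and NDC80 rose (16 and 4 adjusted over the list alone), with a median log2 change of -0.08 and a camera adjusted p of 0.00629 (adjusted p = 0.29 with an estimated correlation). DLGAP5 fell 1.31-fold, ASPM 1.16-fold and the spindle checkpoint kinase TTK 1.12-fold. The call was lost without vector replicate 2 (adjusted p = 0.0506), with the replicate number as a block (0.0551) and among probe sets above the 50th percentile of signal (0.0526). The call of TTK was lost without a variance trend (adjusted p = 0.064). Of 29 S phase genes 10 rose and UHRF1 fell, the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0723). It passed, higher, without FOXC1 replicate 2 (adjusted p = 0.0143). Cyclin E genes CCNE1 and CCNE2 rose 1.34-fold and 1.19-fold, and RRM2 rose 1.18-fold.

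The genes tied to FOXC1 in earlier work were mixed. Of 22 measured 7 rose and 5, CXCR4, TBX1, FGFR4, GATA3 and VIM, fell, the same counts adjusted over the list alone, and 18 of the 22 also stand in other lists. Besides CXCL8, the metalloproteinase MMP7 rose 1.98-fold and the scaffold protein NEDD9 1.96-fold. MMP7 was dim, with signals of 108 in vector and 228 in FOXC1 cells, and its fold was 1.7 with an offset of 64. The list did not pass camera (adjusted p = 0.191), but passed, higher, without vector replicate 1 (adjusted p = 0.0102), without vector replicate 2 (0.00124), with the replicate block (0.0124) and with median centring (0.0128). Of 24 other forkhead factors 3, FOXJ1, FOXK2 and FOXK1, rose and 8 fell (4 and 8 adjusted over the list alone), with a camera adjusted p of 0.095. Besides FOXA1, FOXP2 fell 1.37-fold, FOXQ1 1.37-fold and FOXO4 1.36-fold. This list passed, lower, without FOXC1 replicate 2 (adjusted p = 0.0284).

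Developmental pathways had members in both directions and did not pass camera. In the Hedgehog list 6 of 19 rose and 6 fell (6 and 6 adjusted over the list alone; adjusted p = 0.917), with HHIP and the survival gene BCL2 (1.66-fold) higher and the co-receptors CDON (2.12-fold) and BOC (1.35-fold) lower. Its mean log2 change of 0.16 was positive while its median of -0.04 and the camera direction were negative. It passed in the opposite direction, higher, without vector replicate 1 (adjusted p = 0.00283), without vector replicate 2 (0.00464), with the replicate number as a block (0.0131), with median centring (0.0178) and with fry (0.00776). Without HHIP, left out after seeing the data, the mean log2 change was -0.07 and the list passed under none of these settings (camera direction lower, adjusted p = 0.351 over all 4 arrays). Of 25 Wnt pathway targets 6 rose and 7 fell (7 and 7 adjusted over the list alone; adjusted p = 0.932), with FZD4 (1.92-fold) and WNT5A (1.71-fold) higher and WNT7B (2.10-fold) and LGR5 (1.92-fold) lower. Its median was positive (0.03) while its mean (-0.02) and camera direction were negative. Of 22 Notch pathway genes HEY2 (1.43-fold), NRARP (1.40-fold), JAG1 and MAML2 rose and LFNG (1.64-fold), NUMB (1.18-fold), RBPJ, NOTCH2 and RFNG fell (5 and 5 adjusted over the list alone; adjusted p = 0.709). Its median of -0.008 and mean of 0.006 differed in sign. Of 17 breast stem cell and pluripotency genes ALDH1A3 (1.44-fold), PROCR (1.34-fold) and CD44 rose and 6, LGR5 and EPCAM among them, fell (3 and 6 adjusted over the list alone; adjusted p = 0.331).

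Stress and housekeeping lists did not pass camera either. Of 28 genes of endoplasmic reticulum stress and the amino acid response 9 rose and 9 fell (10 and 9 adjusted over the list alone; adjusted p = 0.959). The cystine transporter SLC7A11, DDIT3 and asparagine synthetase, ASNS, rose 1.62-fold, 1.61-fold and 1.61-fold, and DDIT4 fell 4.56-fold (log2 -2.19 ± 0.05 SE). The median and mean of this list were negative while camera gave the direction higher. Among 18 heat shock genes HSPE1, HSPD1, HSPH1 and DNAJA1 rose and HSPB1 (1.24-fold), HSPA1L (1.23-fold), HSPA2 (1.21-fold) and BAG3 (1.19-fold) fell (6 and 5 adjusted over the list alone; adjusted p = 0.9), with a positive median and a negative mean and camera direction. Of 29 oxidative phosphorylation genes NDUFV2 (1.37-fold), NDUFB3, COX5A and COX5B rose and 8, including SDHD (1.23-fold), NDUFA5 (1.14-fold) and COX6C (1.10-fold), fell (4 and 8 adjusted over the list alone; adjusted p = 0.477). Of 32 ribosomal protein genes 9, including RPS24 (1.14-fold) and RPS16 (1.07-fold), rose and RPS25 (1.13-fold) and RPS23 (1.07-fold) fell (9 and 2 adjusted over the list alone; adjusted p = 0.301). Of 15 expression controls TFRC (1.18-fold), EEF2 and TBP rose and PPIA (1.15-fold), B2M (1.14-fold), PGK1 (1.13-fold), YWHAZ and SDHA fell (4 and 6 adjusted over the list alone; adjusted p = 0.396). Single calls in these lists were lost when 1 array was left out. Without FOXC1 replicate 2 these were HSPA1L (log2 -0.20), NDUFA5 (-0.11) and COX6C (-0.08). Without vector replicate 1 they were HSPA1L (log2 -0.21) and NDUFA5 (-0.15). Without vector replicate 2 they were COX6C (log2 -0.11), HSPA2 (-0.24) and RPS23 (-0.07), and without FOXC1 replicate 1 it was RPS16 (log2 0.05). Without a variance trend the calls of RPS24 (adjusted p = 0.104), RPS16 (0.249), RPS23 (0.206), RPS25 (0.0517), PGK1 (0.0521), PPIA (0.0822), HSPA1L (0.108), COX6C (0.172) and NDUFA5 (0.137) were lost. That of RPS16 was also lost with quantile normalization (adjusted p = 0.161) and median centring (0.242).

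Markers of other cell types were measured as well. Of 17 leukocyte markers CORO1A (1.47-fold), PTPRC (1.39-fold) and CD68 (1.05-fold) rose and LAPTM5 fell 4.41-fold, from 5028 ± 84.8 to 1129 ± 45.4 (SD, n = 2), the same counts adjusted over the list alone, with a camera adjusted p of 0.97 and a negative mean against a positive median. Of 14 fibroblast markers FBN1 (1.65-fold) and DCN (1.55-fold) rose and FBLN1 fell 1.59-fold, the same counts adjusted over the list alone (adjusted p = 0.535), and COL3A1 did not pass (log2 0.17 ± 0.09 SE). The signals of PTPRC and DCN lay below the limit of brightness of 275 in both groups. Of 14 endothelial markers 6 fell, among them PECAM1 (3.15-fold), ROBO4 (1.49-fold) and TIE1 (1.28-fold), and ENG rose, the same counts adjusted over the list alone. This list passed camera with an adjusted p of 0.0218 (adjusted p = 0.29 with an estimated correlation), and the call was lost among probe sets above the 50th percentile of signal (adjusted p = 0.208), without a variance trend (0.0682), with fry (0.0548) and without the genes of neighbouring blocks that shift together (0.404). The call of TIE1 was lost without vector replicate 1 (log2 -0.16) and without a variance trend (adjusted p = 0.156), and that of CD68 without FOXC1 replicate 1 (log2 0.04), vector replicate 1 (0.08) or vector replicate 2 (0.07), with quantile normalization (adjusted p = 0.426), with median centring (0.603) and without a variance trend (0.308).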

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

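The fit over all rows was among the alternatives fixed before the data were examined, and no test here was chosen after a result was seen. Probe sets without a gene symbol lay outside the comparison of named genes, and 10.8% of them passed in a limma fit over all rows. Named genes passed more often in the same fit, with 4015 of 18417. Of the unnamed probe sets 1303 of 12083 passed, 1047 higher and 256 lower in FOXC1 cells, with 2798 at an unadjusted p under 0.05. At least 2-fold changes were seen in 38 higher and 13 lower, and 0 reached 8-fold. Their median log2 change was 0.07, against 0.03 over the named genes. Medians of some named gene families, added after the results were seen, were also positive. They were 0.066 for olfactory receptors, 0.094 for keratin associated and 0.084 for uncharacterised LOC genes. With quantile normalization these became 0.003, 0.049 and 0.051, against 0.003 over all genes. The unnamed probe sets were not counted under quantile normalization or median centring. Whether their balance of directions depends on scaling was therefore not tested. What they detect was not analysed here.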

How the results depend on the processing

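Leaving out the genes of neighbouring blocks that shift together, and leaving HHIP out of the Hedgehog list, were chosen after seeing the data. The other alternatives were fixed before the data were examined. Of the 147 named genes 0 changed direction under the alternatives fixed before that kept them and 17 lost their call under at least 1. Of the 17 lists called, 7 lost the call in at least 1 of 16 alternatives besides the estimated correlation, and 10 lost it in 0 of those that gave a value, which for antigen presentation leave out the one without shifted blocks. The counts of 2925 higher and 2852 lower became 1739 higher with median centring, which shifts every gene down, 1461 and 1790 without a variance trend, 1858 higher over all rows and 50 and 127 with a log2 limit of 1, which only narrows the calls. When each array was left out in turn, with the lone array assumed to vary like the other group, they ranged from 1913 to 2951 higher and from 2059 to 3142 lower, and 16 to 21 lists were called. With an estimated correlation 0 lists passed. For the other shifts in count the cause was not tested.

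Lists whose direction turned were lists not called in the report, and the cause was not tested except for HHIP. The Hedgehog list turned higher above the 25th and 50th percentile (adjusted p = 0.865 and 0.241), with median centring (0.0178), the replicate block (0.0131) and fry (0.00776), and ranged from 0.00283 to 0.986 with an array left out. Without HHIP it was lower under each of the replicate block (0.62), median centring (0.436), fry (0.0613) and either vector array left out (0.596, 0.493). Heat shock turned above the 25th and 50th percentile (0.938, 0.759) and without shifted blocks (0.626). Leukocyte markers turned above the 25th percentile (0.938), with quantile normalization (0.937), median centring (0.294), the block (0.129), fry (0.0548) and without shifted blocks (0.744), with 0.24 to 0.927 with an array left out. Wnt targets turned above the 50th percentile (0.763), with the block (0.983) and without shifted blocks (0.327), with 0.695 to 0.959 with an array left out. Endoplasmic reticulum stress turned with quantile normalization (0.937), median centring (0.869), no trend (0.956), the block (0.983) and without shifted blocks (0.826), with 0.514 to 0.95 with an array left out. Ribosomal proteins turned with quantile normalization (0.937) and median centring (0.948), chemokine receptors with median centring (0.948) and with an array left out (0.614 to 0.959), oxidative phosphorylation with an array left out (0.251 to 1), and the mesenchymal list with fry (0.232).

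The FOXC1 transcript and its alternatives were not run. The antigen presentation list had under 5 genes left without shifted blocks and has no value there. Dim transcripts limit the folds, since signals near the offset of 16 carry little information. Some genes named with a fold, such as MMP7, MMP3, CCL20, FOXP2, CCR1, PTPRC and DCN, lay below the limit of brightness of 275 in both groups.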

Other observations

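The comparison of other splits and the tests on luminal cells, scaling and culture state were chosen only after the results were seen. The tests on neighbouring genes were written before theirs.

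Several gene families were counted apart from the lists, although some solute carriers, such as SLC7A11, stand in both. Small nucleolar and Cajal body RNA genes, which guide the modification of other RNAs, were higher in 61 and lower in 8 of 192, with a median log2 change of 0.14, and in 55 and 9 after quantile normalization and 58 and 11 after median centring. Spliceosomal and other small RNA genes were higher in 12 and lower in 1 of 29. Histone genes were higher in 22 and lower in 8 of 73, with 14 and 10 after median centring. Zinc finger ZNF genes were higher in 109 and lower in 36 of 439, with 75 and 49 after median centring. Solute carriers were higher in 71 and lower in 47 of 376, but 48 and 58 after median centring. Protocadherins were higher in 5 and lower in 7 of 42 (1 and 7 after quantile normalization), microRNA genes in 14 and 7 of 189 (8 and 8 after quantile normalization), olfactory receptors in 11 and 3 of 360 (5 and 3 after quantile normalization), keratin associated protein genes in 7 and 0 of 68 (7 and 2) and uncharacterised LOC genes in 10 and 3 of 85 (7 and 3). These are counts with no enrichment test.

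The limma fit called 5777 genes for the real grouping and 0 for each of the 2 other splits of the 4 arrays into pairs (unadjusted p under 0.05 in 96 and 127 genes). Only the real split gave as many, 1 of 3, and with 3 splits a share under 0.05 cannot be reached. Each other split puts 1 FOXC1 and 1 vector array in each group. Any difference between the real groups then adds to the spread and hinders calls, so that the 0 calls do not measure false calls.

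Neighbouring genes shifted together between the groups. Over 184 blocks of about 100 neighbouring genes, the SD of the mean log2 change was 0.0449, which is 2.03 times that of shuffled gene orders (permutation p = 0.001, the smallest that 1000 shuffles can give), and the ratio was 2.14 in genes brighter than the median gene but 1.16 in dimmer ones. In the most shifted blocks, 45 of 88 genes from C18orf54 to PARD6G were higher (mean 0.27) and 48 of 98 genes from RNF31 to MAP4K5 were lower (mean -0.18). The named genes were not sorted by block here, so that some of their changes may be part of these shifts. A trend along the gene order that also varies between replicates is argued against, since block means within a group correlated with those between groups at 0.073 at most in size, although the ratio within the FOXC1 pair was 1.43. As a hypothesis, the FOXC1 and vector populations may differ in copy number or sub-line, while regional regulation of expression remains open, and without the 4 most shifted blocks the ratio was 1.59. Shifts of whole blocks do not account for most large changes. In blocks shifted the same way lay 16.4% of the 177 genes changed at least 2-fold, against 13% of other genes. The 95% Wilson interval of the 16.4% was 11.7% to 22.5%. A copy number change of a short region, or a sub-line difference, need not shift a block and remains open for the large changes.

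The falls of CLDN4, CLDN7, SPDEF and FOXA1 could arise if luminal epithelial cells were mixed into the vector cultures. Such cells bring all their abundant transcripts. The median log2 change of CDH1, EPCAM, KRT19, RAB25, ELF3 and PRSS8 was 0.046, but the members went both ways, which keeps this open. EPCAM (log2 -0.58, adjusted p = 2.27e-07) and KRT19 (-0.24, 8.85e-06) fell in limma, while the other 4, at or below a signal of about 280, were not lower by 2 SE. A response to FOXC1 and a difference between the populations from before the transfection also remain open.

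The hypoxia and glycolysis list had a median log2 change of -0.25 as deposited, -0.275 with quantile normalization and -0.291 with median centring. The median over all genes was 0.033, 0.003 and -0.009 under the same settings, so the list lay below it in each. Both alternatives moved the median over all genes down, so that the list could hardly have come nearer to 0. They therefore cannot exclude scaling between arrays as a part of the fall. A different density or oxygen state of the cultures could lower hypoxia genes. Of 11 HIF targets 10 fell (median log2 -0.43), and of 12 glycolysis enzymes 5 fell and 0 rose, with a median of -0.053 that was too small to decide. Culture state is confounded with the groups and cannot be told apart from an effect of FOXC1.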
